A study of Mus musculus with 2 samples.

How the data were processed

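Trimethylation of histone H3 at lysine 36 (H3K36me3), a mark laid down over the bodies of transcribed genes, was profiled by chromatin immunoprecipitation and sequencing in neural tube of B6NCrl mouse embryos at 15.5 days. Per the labels, each library was made from tissue of male and female embryos pooled, 78 embryos for replicate 1 and 62 for replicate 2. These replicates form 1 group, called library 1 and library 2 here, so no comparison between groups and no test across samples was possible, and errors are the SD of 2 libraries. The labels name no treatment, and control libraries were not used here.

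The authors deposited 4 peak lists on mouse assembly mm10: 1 for each library, 1 called on both libraries together (the pooled list) and 1 of replicated peaks. The deposited text says that each library's list came from 1 alignment, with technical replicates combined, and from further input files of unstated kind. It says that the replicated list was derived from both single-library lists and the pooled list. The aligner, the peak caller, its threshold, the control and the rule that made a peak replicated are not given in the sources used here. In the deposited lists, 1 column holds the ratio (fold enrichment of the peak over control, as the narrowPeak format defines its signal value), and the next columns hold the -log10 p-value and the -log10 q-value of the peak within its own list. These columns were checked against the values, which matched those units. Read counts were not used here, so the depth of each library is unknown and no interval or lower limit from read counts is given. The 1 Wilson interval is over genes, which are not independent, and covers counting error only. Peaks below the caller's threshold are missing, so an uncovered gene is a gene without a listed peak.

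Peaks on chromosomes 1 to 19, X and Y were used, and those on unplaced and unlocalised sequences were left out of the comparisons. Genes, transcripts and exons came from GENCODE release M21, and chromosome lengths, gaps (runs of at least 100 unknown bases) and sequence from the RefSeq copy of the same assembly. The main measure was gene-body coverage, the percent of bases from a gene's annotated start to its end that lay in replicated peaks, computed for 21938 protein-coding genes. A gene with at least 10% coverage was called marked. The same measures were computed from each library's own list and are given as mean ± SD (n = 2). Coverage is a share of bases in called peaks, not a level of the mark.

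Overlap of the libraries was the share of 1 library's peaks with at least 50% of their length in the other's peaks, and the Jaccard index of covered bases, beside 20 random placements of the peaks within their chromosomes. Agreement across genes was Pearson's r and Spearman's rho, without a p-value because genes are not independent replicates. Bases were assigned in the order promoter (within 1 kb of any annotated transcript start), 5' UTR, coding exon, 3' UTR, other exon, intron and intergenic. Position along genes used 10 equal parts of protein-coding genes of at least 5 kb that overlapped no other gene. For background, each gene's length was placed once at random in intergenic sequence.

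Gene lists, 34 in all, were fixed before the data were examined: 30 hand-written lists (577 symbols, of which 3 matched by synonym and 0 were missing) and 4 families taken by gene name. These were neuronal, progenitor, cell cycle, spinal motor neuron, spinal interneuron, transmitter, glial, axon guidance and protocadherin lists; lists of other cell types a dissection could carry (sensory ganglion, meninges, endothelium, blood, muscle, hepatocyte, epidermis); forebrain, testis and Hox lists; and lists of general, chromatin, imprinted, noncoding and disease genes. The families were olfactory receptors, vomeronasal receptors, replication-dependent histones, and genes named Zfp and a number, many of which encode KRAB zinc fingers. Each list was set beside 10000 random lists of protein-coding genes of the same size, drawn with replacement and matched on 10 groups of gene length. The percentile of the list's median coverage was fixed before the data were examined. The percentile of its number of marked members was added after seeing the data, because for many lists most random lists had a median of 0. A list is described as above or below random lists when its percentile of marked members, with ties split evenly, lay outside the central 95% range. A count equal to the lowest value of the printed range can lie outside by this rule, and is described as at the end of the range. For 7 pairs of lists, the difference of median coverage was ranked among 10000 reassignments of the genes to the pair, not matched on gene length. These ranks describe genes, not embryos. Genes of a list often lie or act together, which the random lists do not copy.

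Named genes were chosen by a rule fixed before the data were examined: for each list the 3 members with the highest coverage and the 1 with the lowest (ties in alphabetical order), the 10 protein-coding genes of at least 10 kb with the highest coverage and the 10 with the most covered bases among genes overlapping no other protein-coding gene, the 5 genes of at least 10 kb with the largest difference between libraries in each direction, and a fixed set (Actb, Gapdh, Tubb3, Sox2, Olig2, Mnx1, Chat, Isl1, Gad1, Slc17a6, Slc6a5, Hoxb8, Hoxc10, Hoxa13, Foxg1, Alb, Myod1, Xist and Setd2). Genes named outside this rule are introduced as chosen after their values were seen. Positions are counted from 1 on mm10. For zinc finger peaks, 31-base words were counted across the genome, beside 500 unmatched peaks of at least 1 kb drawn at random from other protein-coding genes. Tests of their fold used comparison peaks matched on base composition and width.

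Alternatives were peaks with a -log10 q of at least 2, each library's own list, the pooled list, peaks within 1 kb merged, an overlap of 1 base or 80%, marking limits of 5% and 20%, genes overlapping no other gene, minimum gene lengths of 2 kb and 10 kb, no length matching, coverage downstream of each gene's midpoint, a promoter window of 2 kb, and equal numbers of covered bases in both libraries. Added after seeing the data were the percentile of marked members, promoters only at the 5' end of protein-coding genes, and lists without members on chromosome X. The coverage and list code was tested on simulated data: 2000 of 2000 simulated intervals gave the right number of covered bases, 3% of 200 random lists of 24 genes fell outside the central 95% range, and lists planted with 16 marked members lay above it in 100% of runs. Values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0, and plots were drawn with matplotlib 3.10.9.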

Results

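H3K36me3 peaks were listed for neural tube of mouse embryos at 15.5 days in 2 libraries of 1 group, each from pooled male and female embryos (78 in library 1, 62 in library 2). The labels name the tissue, the age and the mark but no treatment or contrast, so the values describe where the mark was called and in which genes. Library 1 held 181763 peaks covering 98.6 Mb and library 2 held 156252 covering 80.9 Mb, a mean of 169008 ± 18039 peaks and 89.8 Mb ± 12.6 (SD, n = 2). Their median widths were 346 and 345 bases and their median fold enrichments 2.97 and 3.01. A -log10 q of at least 2 was reached by 86.3% of peaks in library 1 and 77.5% in library 2. The pooled list held 172619 peaks (120.4 Mb) and the replicated list 115017 (105.2 Mb), with a median width of 580 bases, a median fold of 2.99 and a highest fold of 11.99. Joining peaks up to 1 kb apart left 54396 in library 1 and 47019 in library 2. Joined replicated peaks formed 38572 domains, the widest of 103397 bases. Read depth is unknown.

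Coverage of genes in the 2 pools of embryos was closely correlated, though its level was higher in library 1. At least 50% of the length of 53.1% of library 1's peaks lay in peaks of library 2, against 3.49% for randomly placed peaks, and 72.1% of library 2's peaks lay in those of library 1, against 4.28%. With an 80% overlap these shares were 32.5% and 52.9%. Covered bases shared a Jaccard index of 53.0% (62.2 Mb in common), against 1.97% at random. Across 21938 protein-coding genes, coverage in library 1 and library 2 had a Pearson r of 0.979 and a Spearman rho of 0.961. Without the 10040 genes at 0 in both libraries, these were 0.968 and 0.959. Genes are not independent replicates.

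Every replicated peak had the coordinates of a pooled peak, and the replicated list took 66.6% of the pooled list. Of the 115017 replicated peaks, 91482 touched a peak in each library, and 78.8% met a 50% overlap of either peak in both libraries. The rest did not touch a listed peak in each library, so a replicated peak was not always one listed in both. Among the 57602 pooled peaks left out, 3 met that overlap, 26075 touched library 1 alone, 12946 touched library 2 alone and 17732 touched neither. The peaks left out had a median fold of 2.28 and a median width of 234 bases.

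The mark lay in gene bodies and was densest over coding exons and towards the 3' end. Introns held 59.6% of replicated bases against 38.3% of the genome, coding exons 8.28% against 0.942%, and 3' UTRs 7.10% against 1.17%. Coding exons thus held 8.79 times their share of the genome, 3' UTRs 6.08 times and introns 1.55 times. Intergenic sequence held 4.34% of the bases against 52.4% of the genome, 0.0827 times its share. In the libraries' own peaks these shares were 59.2% ± 0.901 for introns, 8.60% ± 0.370 for coding exons, 6.999% ± 0.127 for 3' UTRs and 4.36% ± 0.213 for intergenic sequence (SD, n = 2). Smaller classes were 5' UTRs at 0.104% (0.104% ± 0.00552 in the libraries) against 0.0332% of the genome, and other exons at 3.58% (3.55% ± 0.0514) against 1.04%. Promoters of any annotated transcript, starts inside genes included, held 17.05% (17.2% ± 0.571) against 6.05%, and 29.6% with a 2 kb window. Promoters at the 5' end of protein-coding genes alone, a definition chosen after seeing the data, held 0.413% of the bases against 1.56% of the genome, 0.265 times their share.

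Along 8833 protein-coding genes of at least 5 kb that overlapped no other gene, mean coverage rose from 1.155% in the first of 10 equal parts to 13.6% in the fourth and 22.9% in the ninth, and was 21.8% in the last. The libraries' own peaks covered 1.01% ± 0.238 of the first part, 19.8% ± 1.99 of the ninth and 18.5% ± 1.99 of the last (SD, n = 2). The part of genes downstream of the midpoint had 2.25 times the coverage of the part upstream of it (2.29 ± 0.0599 in the libraries' own peaks). In the 3010 marked genes among them, coverage rose from 2.98% to 64.8% in the ninth part and was 59.6% in the last. The mark passed the annotated gene end: the first 1 kb downstream of marked genes was covered at 44.5% and the fifth at 14.9%. Upstream, the first 1 kb was covered at 0.499% and the fifth at 10.5%. Since coverage also rose with distance upstream, coverage in the outer steps need not belong to the gene itself.

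**Figure D1:**
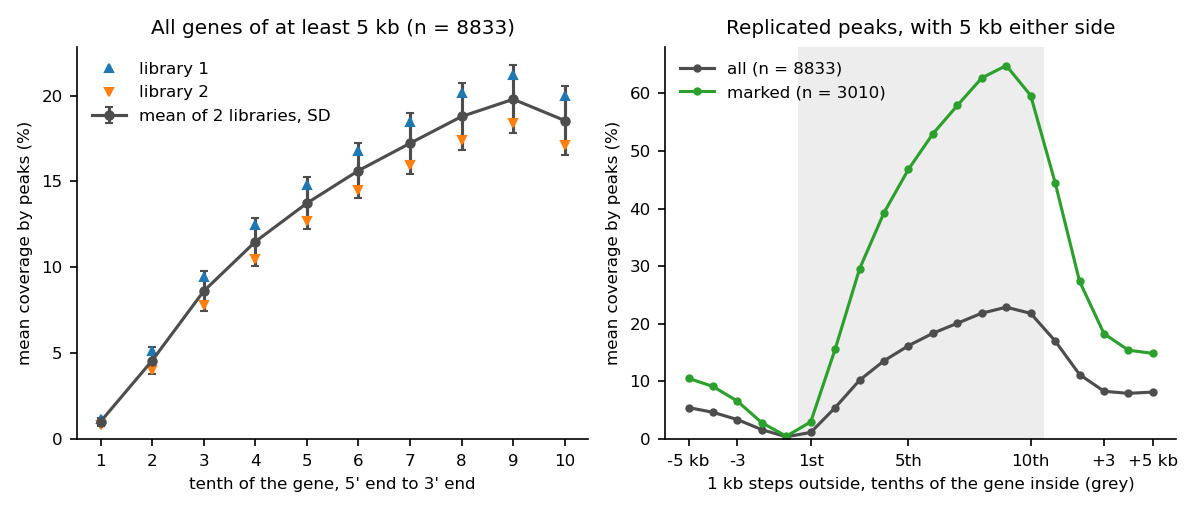
Mean coverage by replicated peaks (percent of bases, vertical axis) in 10 equal parts of protein-coding genes of at least 5 kb and in 1 kb steps outside them (horizontal axis), for all 8833 genes, for the 3010 marked genes and for each library's own peaks. Coverage of all genes rose from 1.155% in the first part to 22.9% in the ninth.

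Of 21938 protein-coding genes, 7846 (35.8%) were marked and 11192 had no covered base. The libraries' own lists marked 7873 and 7106 genes, of which 7026 were marked in both, 847 in library 1 alone and 80 in library 2 alone, a mean of 7490 ± 542 (SD, n = 2). Intergenic placements of the same lengths passed the 10% limit in 0.119% of 21845 cases (93 genes were too long to place). Restricting to genes that overlapped no other gene left 3332 marked of 11725 (28.4%). The share marked rose with gene length across 10 groups of equal size from 8.80% in the shortest (up to 2.74 kb) to 49.95% in the seventh (25.1 to 36.4 kb) and was 18.96% in the longest group (from 109.9 kb), where 66.5% of genes had some covered base. Noncoding genes that overlapped no protein-coding gene were seldom marked: 72 of 5358 lincRNAs (1.34%), 2 of 209 antisense genes (0.957%), 50 of 7788 processed pseudogenes (0.642%), 6 of 2483 unprocessed pseudogenes (0.242%) and 28 of 1203 genes yet to be experimentally verified (2.33%). Short RNA genes reached 8.30% for miRNAs (76 of 916) and 4.15% for snoRNAs (40 of 964).

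Exosc10 had the highest coverage among genes of at least 10 kb that overlapped no other protein-coding gene. This gene (ENSMUSG00000017264, chromosome 4, 148558429 to 148582401), which encodes a catalytic subunit of the nuclear RNA exosome, was covered at 91.2% by replicated peaks and at 85.6% ± 2.66 by the libraries' own (SD, n = 2). It was followed by Trrap, a scaffold of histone acetyltransferase complexes (91.1%, libraries 85.7% ± 2.31), the splicing factor Sf3a1 (90.8%, libraries 86.2% ± 3.61), the corepressor Sin3b (89.98%) and the histone H2B ubiquitin ligase Rnf40 (89.96%). The other members of the highest 10 were Polr3a (89.9%), Scrib (89.2%), Kdm4a (89.1%), Sec24c (89.1%) and Ints1 (89.0%). The most covered bases lay in long genes: Vps13d held 133.4 kb of the gene's 222.4 kb, Wdfy3 122.2 kb, the cytoskeletal linker Macf1 116.3 kb, Fry 111.4 kb and Dst 106.4 kb. Hectd4, Herc2, Clasp1, Trio and 4930402H24Rik held 98.1, 96.6, 94.9, 93.2 and 91.8 kb.

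Lists of broadly expressed and chromatin genes stood far above random lists matched on gene length, whose mean number of marked members and 95% range are given in parentheses for each list. Of 32 ribosomal protein genes, 30 were marked, against a mean of 7.93 in random lists (95% range 4 to 13), with Rps3 at 78.9% (71.8% ± 1.05 in the libraries' own peaks; SD, n = 2), Rps5 at 74.1%, Rps7 at 72.5% and Rps23 lowest at 4.72%. Splicing and RNA-binding genes had 21 of 26 marked (random 9.67, 5 to 14), led by Fus (78.8%, libraries 72.0% ± 4.85), U2af1 (71.9%) and U2af2 (69.5%), while the neuronal splicing regulator Rbfox1 was at 0.388%. Polycomb and trithorax genes had 19 of 20 marked (random 8.69, 5 to 13), led by the H3K4 methyltransferase gene Kmt2d (84.1%, libraries 81.3% ± 0.393), Wdr5 (71.6%) and Phc1 (62.4%), with Bmi1 lowest at 8.08%. Among genes of H3K36 methylation and its readers, 16 of 20 were marked (random 8.10, 4 to 12): the demethylase gene Kdm4a (89.1%, libraries 83.9% ± 0.857), Brpf1 (76.7%), the reader gene Psip1 (60.5%) and Setd2, which encodes the H3K36 trimethylase (39.7%, libraries 33.2% ± 2.13), with Phf19 at 0. Housekeeping genes had 17 of 24 marked (random 9.04, 5 to 14), including Eef2 (79.0%, libraries 72.4% ± 0.0723), Hsp90ab1 (77.8%), Atp5b (71.3%), Actb (56.9%) and Gapdh (18.7%), with B2m at 0. Median coverage of these lists was 48.3%, 46.9%, 42.8%, 40.1% and 30.6%, at percentiles 100, 100, 99.9, 100 and 99.5 of random medians.

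Pan-neuronal genes were marked more often than random genes of their length. In this list 16 of 28 were marked, against 8.80 (4 to 14), and its median coverage of 13.4% lay at percentile 99.5 of random medians. It was led by Uchl1, a deubiquitinase gene abundant in neurons (ENSMUSG00000029223, chromosome 5, 66676091 to 66687234; 61.5%, and 50.8% ± 11.6 in the libraries' own peaks; SD, n = 2), the synaptic vesicle gene Vamp2 (50.1%, libraries 29.5% ± 3.00) and Stmn3 (41.3%, libraries 35.8% ± 11.7). Tubb3, a neuronal tubulin, was covered at 34.99% (31.1% ± 2.05), and Dcx, on chromosome X, held no replicated base. The list's median stood at percentile 97.02 without length matching, and was 7.69% in library 2's own peaks and 12.5% in library 1's. Neurological disease genes had 13 of 22 marked (random 7.24, 3 to 11) with a median of 17.5% at percentile 99.8, led by Tsc2 (86.4%, libraries 80.3% ± 1.2), Smn1 (68.8%) and Tsc1 (64.1%), with Snca at 0. Among its members overlapping no other gene the median stood at percentile 94.5, and without length matching at 97.3. Clustered protocadherins had 10 of 16 marked (random 4.59, 1 to 8) with a median of 11.98% at percentile 98.3, led by Pcdhgb1 (45.5%), Pcdhga1 (45.04%) and Pcdhga5 (42.5%), with Pcdhb14 at 0. Many of these genes share bases with each other, and library 2's own peaks marked 6 of them, at percentile 88.8 of random marked counts. A limit of 20% gave percentile 86.9 and coverage downstream of the midpoint 69.2. Axon guidance genes were like random genes, with 5 of 22 marked (random 5.43, 2 to 9): Plxna2 (31.1%), Cntn2 (22.2%) and Efnb3 (17.7%) were highest and Efna5 was at 0.

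Transmitter genes lay inside the range of random lists. In the inhibitory list 1 of 12 was marked (random 3.94, 1 to 7), the GABA transporter gene Slc6a1 (35.96%, libraries 26.9% ± 4.69), followed by Glra1 (6.33%) and the glycine transporter gene Slc6a5 (2.28%), with Gad1 at 1.12% and Gabra2 at 0. Its count was at the lower end of the range, at percentile 2.71, and 1.51 in the pooled list. The glutamatergic list had 2 of 12 marked (random 3.46, 1 to 7), the receptor gene Grin1 (57.8%, libraries 50.6% ± 8.81) and the scaffold gene Dlg4 (42.8%), followed by Gria2 (5.70%) and the vesicular transporter gene Slc17a6 (4.03%), with Gria3 at 0. Cell cycle genes matched random lists with 8 of 20 marked (random 8.28, 4 to 13), led by Cdk4 (70.2%, libraries 65.8% ± 1.58), Ccna2 (52.9%) and Mcm6 (51.6%), with Aurkb at 0.

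Spinal interneuron and motor neuron genes had no marked member in the replicated list. None of 30 spinal interneuron transcription factors was marked (random 10.9, 6 to 16); Pax2 reached 0.566% and Barhl1 and Barhl2, like the other 27 members, were at 0. None of 16 spinal motor neuron genes was marked (random 5.59, 2 to 9): Etv4 (0.499%), Ret (0.426%) and Slit3 (0.362%) were highest, and Mnx1, Isl1, Chat and Aldh1a2 were at 0. Across both lists, 8 of 46 genes (17.4%) had any base in the pooled list, against 52.5% of random genes of the same length and 0.0915% of olfactory receptor genes, which are shorter (median 5.99 kb against 15.48 kb). Neural progenitor and radial glia genes had 2 of 24 marked (random 6.56, 3 to 11), Msi1 (50.3%, libraries 42.2% ± 10.1) and Vim (25.1%, libraries 16.6% ± 2.48), with Notch1 at 9.52% and Sox2, Olig2 and Ascl1 at 0. In library 1's own peaks 3 progenitor genes were marked, at percentile 4.15, inside the central range, as were the pooled list at 2.58 and members overlapping no other gene at 20.8. Astrocyte and oligodendrocyte genes had 2 of 18 marked (random 6.12, 3 to 10), Mog (12.5%) and Slc1a2 (11.7%), with S100b at 4.39% and Aldh1l1 at 0, and no member was marked in both libraries' own lists: library 1's marked Slc1a2 (12.3%) but not Mog (8.39%), and library 2's marked Mog (10.4%) but not Slc1a2 (7.68%). Members overlapping no other gene stood at percentile 4.29. Mog lies 108 bases from Zfp57, which was covered at 61.0%.

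Hox genes, which set position along the body axis, were mostly unmarked. Of 15 anterior members, Hoxa4 (17.8%, libraries 12.2% ± 5.06) and Hoxa5 (14.96%, libraries 6.30% ± 8.91) were marked (random 4.34, 1 to 8), followed by Hoxd3 (4.96%), with Hoxa1 at 0. Library 2's own peaks marked no anterior member, at percentile 0.315. The central group had 0 of 12 marked (random 3.32, 1 to 6), with Hoxa6 at 2.92% and Hoxa7, Hoxa9 and Hoxb8 at 0. The posterior group had 0 of 12 marked (random 2.94, 0 to 6), including Hoxc10 and Hoxa13. This lay at the lower end of the random range, and 3.41% of random lists had as few. Forebrain transcription factors had 0 of 18 marked (random 6.37, 3 to 10), with Bcl11b at 2.02% and Foxg1, Dlx1 and Dlx2 at 0. Among members overlapping no other gene, forebrain factors stood at percentile 2.85, inside the central range, and posterior Hox genes at 11.3.

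Markers of other cell types that a dissection could carry were unmarked, apart from 3 blood and microglia genes. No gene was marked among 16 of sensory ganglion and Schwann cells (random 5.88, 2 to 10; highest Pmp22 at 2.17%, Scn9a at 0.430%, Avil at 0), 18 of meninges and mesenchyme (random 6.85, 3 to 11; Pdgfrb 3.83%, Col2a1 1.502%) or 16 of endothelium (random 5.35, 2 to 9; Eng 0.654%). The same held for 16 genes of skeletal muscle (random 5.13, 2 to 9; Ttn 6.16%, Neb 0.219%, Myod1 at 0), 18 of hepatocytes (random 6.41, 3 to 10), all of them at 0 including Alb, 14 of epidermis (random 4.35, 1 to 8), all at 0, and 16 of testis germ cells (random 5.13, 2 to 9; Acr 1.82%). Among the 7 sensory ganglion, 6 muscle and 9 epidermis genes that overlapped no other gene, again 0 were marked, at percentiles 4.38, 9.335 and 4.62, inside the central range. Blood and microglia had 3 of 16 marked (random 4.83, 2 to 8), each beside or across a covered gene. Cd68 (100%, libraries 98.8% ± 1.64) lies 783 bases from Eif4a1 (49.7%), Fcer1g (17.6%, libraries 11.4% ± 11.4) lies 488 bases from Ndufs2 (56.6%), and the annotated span of Cx3cr1 (16.6%, libraries 13.96% ± 0.550) overlaps Wdr48 (72.4%), with Aif1 at 0. These neighbours, and Zfp57 beside Mog, were looked up after the markers' values were seen. The span of Cx3cr1 also overlaps Gorasp1 (55.0%). No share of all genes lying beside a covered gene is given here, so whether the neighbours account for the markers' coverage was not tested. Leading genes of other lists also overlap protein-coding genes, such as Cdk4 (Tspan31), Ccna2 (Exosc9) and Nnat (Blcap).

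Imprinted genes had 8 of 24 marked (random 8.23, 4 to 13), led by the maternally expressed noncoding gene Meg3 (69.4%, libraries 55.0% ± 9.78), Nnat (60.3%) and Igf2r (53.0%), with Cdkn1c at 0. Long noncoding RNA genes had 9 of 22 marked, against 7.77 (4 to 12) in random lists of protein-coding genes and 2.73% of all annotated lincRNAs (160 of 5854): after Meg3 came Mirg (64.1%) and Snhg1 (59.7%), with Dlx6os1 and Xist at 0. Among families, none of 1093 olfactory receptor genes was marked (random 372.7, 343 to 403; highest Olfr543 at 5.53%), none of 327 vomeronasal receptor genes (random 116.9, 101 to 133) and none of 67 replication-dependent histone genes (random 7.41, 3 to 13). Neither vomeronasal nor histone genes had any covered base. Library 1's own peaks marked 1 olfactory receptor gene. Genes named Zfp and a number were marked in 258 of 365 cases (random 152.0, 134 to 170) with a median coverage of 31.9% (28.0% ± 3.08 in the libraries), led by Zfp869 (92.8%, libraries 88.9% ± 2.27), Zfp110 (86.6%) and Zfp335 (86.4%), with Zfp114 at 0. They also held 58 of the 100 peaks of highest fold.

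**Figure D2:**
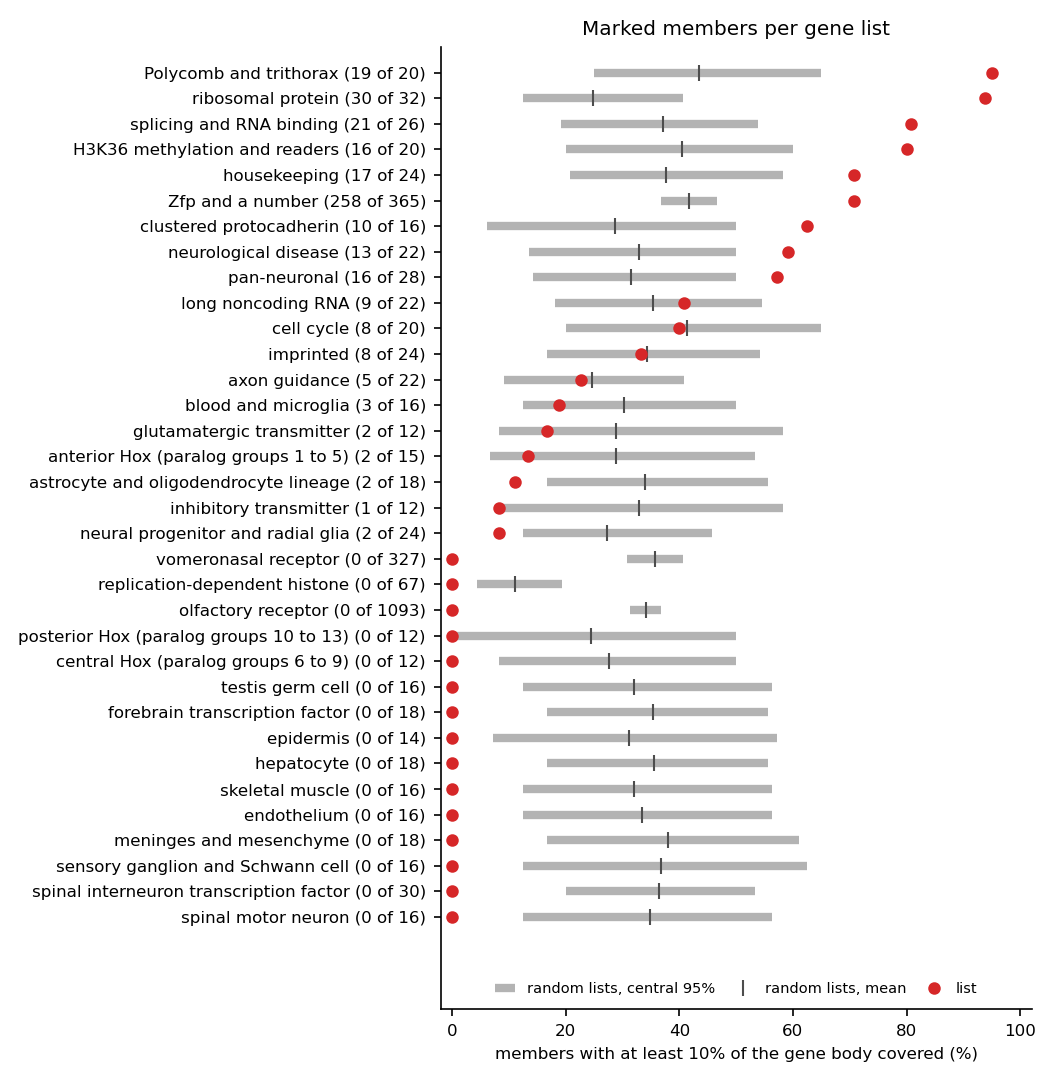
Percent of each list's members that were marked (red points, horizontal axis), beside the mean and central 95% range of 10000 random lists matched on gene length (tick and grey bar). Ribosomal protein genes stood at 30 of 32 marked and spinal interneuron transcription factors at 0 of 30.

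Compared directly, pan-neuronal genes were covered more than progenitor genes, with medians of 13.4% and 0 and 57.1% against 8.33% marked; 0.32% of 10000 reassignments of the genes gave as large a difference of medians and 0.05% of marked shares. The same difference of medians from hepatocyte genes was reached by 1.28% of reassignments and that from skeletal muscle genes by 3.13%. Ribosomal protein genes exceeded housekeeping genes by 17.7 points in the median, which 12.6% of reassignments reached, while their marked shares of 93.8% and 70.8% differed by an amount that 2.89% reached. The direction of that difference stayed when either library was left out, but its rank was lost. The shares were 87.5% and 70.8% without replicate 1, which 17.33% of reassignments reached, and 90.6% and 70.8% without replicate 2, which 7.65% reached. In the pooled list 5.74% reached the difference, and downstream of the gene midpoint 21.1%. Downstream of the midpoint their medians differed by 45.4 points, which 0.5% of reassignments reached. Inhibitory minus glutamatergic genes gave -1.23 points (21.8% of reassignments). Anterior and posterior Hox genes, and spinal interneuron and forebrain transcription factors, had medians of 0 on both sides, so their difference of 0 separates nothing. In library 2's own peaks the pan-neuronal differences were 7.69 points. These reassignments were not matched on gene length, which had a median of 64.7 kb in the pan-neuronal list and 5.31 kb in the progenitor list.

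Library 1 covered more of most genes. Over 11898 genes covered in either library, coverage in library 1 minus library 2 had a median of 3.07 points, and 85.9% of the genes were higher in library 1. With as many covered bases taken from each library the median was 0 and 48.6% were higher in library 1, a balance that the scaling itself largely sets. Among genes of at least 10 kb, the largest differences towards library 1 were in Timp4 (42.3% in library 1, 14.1% in library 2), which overlaps the synapsin gene Syn2 (looked up after this value was seen), then Trmt44 (79.5% and 54.7%), Fuca1 (40.2% and 17.01%), Fsd1 (63.2% and 40.0%) and Hemk1 (33.2% and 10.1%). Towards library 2, differences among genes of that length were smaller: Ythdf1, which encodes a reader of methylated RNA (45.1% and 53.9%), Mbd4 (8.03% and 16.6%), Naaladl1 (18.2% and 26.7%), Lman2 (55.2% and 63.3%) and Kri1 (62.1% and 70.1%). Shorter genes also differed in places, and 2 were chosen after their values were seen. Scg2 (33.3% and 7.63%) differed by less than Timp4, and Rpl37 (22.4% and 49.8%) by more than the longer genes named towards library 2. Each side of these comparisons is 1 library, so no test was possible.

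Genes on chromosome X were marked far less often than autosomal genes. On X, 90 of 948 protein-coding genes (9.49%) were marked, against 37.3% of 20807 autosomal genes, a difference of -27.8 points; the lowest autosome was chromosome 14 at 28.4% and the highest chromosome 8 at 46.5%. Library 2's own peaks gave -26.7 points and library 1's -27.1. Replicated peaks covered 4.34 kb per Mb of X, against 27.0 on chromosome 3, the lowest autosome, and 72.5 on chromosome 11, the highest. The marked genes of X had a median coverage of 21.9% against 39.9% on autosomes, and the highest peak in each had a median fold of 3.36 against 4.29 in marked autosomal genes of the same length. Chromosome Y held 5 replicated peaks and 0 of its 183 protein-coding genes were marked. Of the hand-written lists' protein-coding members, 4 of 15 on X were marked (26.7%, 95% Wilson interval 10.9% to 51.95%), against 171 of 533 elsewhere (32.1%). The 4 were Syp, Rps4x, Pgk1 and Rbbp7, named after their values were seen. The noncoding X-linked members Xist and Tsix were not counted. Both libraries mixed male and female embryos, so X could not be compared between the sexes.

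**Figure D3:**
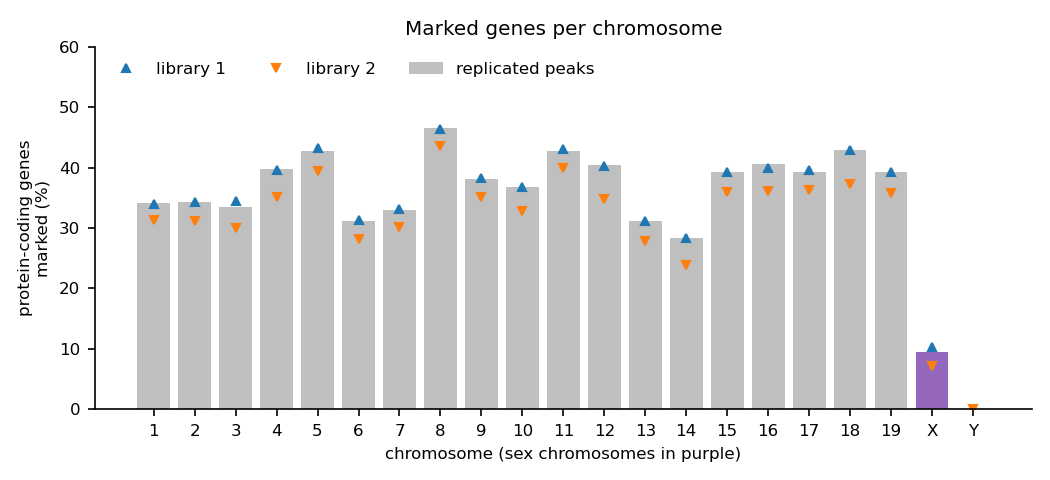
Percent of protein-coding genes marked on each chromosome (bars, replicated peaks) with the values from each library's own peaks (points). Chromosome X stood at 9.49%, below all 19 autosomes.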

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

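The tests here that were chosen only after the result was seen are the pooled-list test for chromosome X, the test of zinc finger peaks at the top of the fold scale and the gene-length test for lineage regulators. The replicated list also held 40 peaks on 13 unplaced and unlocalised sequences, which the comparisons leave out; they drew attention as signal outside the main measurement. Their median fold was 2.10 and their highest 5.15, and 22 touched a peak in each library.

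Genes on chromosome X were marked less often. Gene length, exon number and provisional symbols do not account for it by themselves. Among genes without a provisional symbol, of at least 10 kb and with at least 5 exons, X stood at -33.5 points against autosomes (13.4% and 46.8% marked). That test did not match genes on what they do, so this part of gene content remains open. The 15 protein-coding X members of the hand-written lists stood at 26.7% (95% Wilson interval 10.9% to 51.95%) against 32.1% elsewhere. They were too few to settle it. Their interval lay above the 9.49% of all X genes, but hand-picked members are not a random draw of X genes. The interval therefore does not decide on gene content. The replication filter does not by itself account for the difference either, since the pooled list gave -26.8 points, although that list has a threshold of its own. From the replicated to the pooled list, the share marked rose from 9.49% to 13.2% on X and from 37.3% to 39.9% on autosomes. Some part played by the filter is therefore not excluded. Fewer marked copies per cell is a candidate explanation: the highest fold of marked X genes was 0.784 times that of length-matched autosomal genes, past the limit set before the test. Fold does not count copies, and weaker marking of each copy would lower it too, so the ratio does not single out this explanation. Silencing of 1 X in female cells is another candidate. Of 8 genes listed as escaping it, 7 were found among the protein-coding genes. Of these, 3 were marked, at percentile 98.8 of random X lists (Kdm5c, Eif2s3x and Ddx3x, named after their values were seen). Escape genes are also broadly expressed, and a difference in sex stays untested because both pools mix males and females.

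Genes named Zfp and a number held 58 of the 100 peaks of highest fold, 46 of those 58 touching a gene's last exon, although they held 1.96% of all replicated peaks. Sequence shared between gene copies is argued against: a median of 3.47% of 31-base words in those peaks occurred elsewhere in the genome. The median was 0.901% in 500 comparison peaks, drawn at random among those of at least 1 kb and not matched. Zinc finger peaks in general had a median fold 1.096 times that of peaks matched on base composition and width, within the limit set before that test. The typical zinc finger peak thus stood little above matched peaks (3.28 against 2.99). All replicated peaks also had a median of 2.99, so the ratio cannot show what composition and width account for. At the top of the fold scale, tested after that ratio was seen, 60 zinc finger peaks stood against 3.33 expected from matched peaks, 18.0 times as many. Control signal in these exons was not analysed here, so a low control remains open, and no biological explanation was tested.

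The 46 genes of the spinal motor neuron and interneuron lists had no marked member. Short genes are argued against, since the 95% range of length-matched random lists was 10 to 23 marked members. With both lists joined, this repeats the length-matched comparison given above for each list, so it is not separate support. Signal below the threshold remains open: any pooled-list base was seen in 17.3 points more of these genes than of olfactory receptor genes, between the 5 and 20 points set as limits before the test, and the genes were not matched on length (median 15.48 kb against 5.99 kb), which by itself raises that share. A weak or sparse signal and absence of the mark cannot be told apart here, because the lists hold only called peaks, and no biological explanation was tested.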

How the results depend on the processing

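The alternatives chosen only after seeing the data were the percentile of marked members, promoters at gene 5' ends and lists without X members. Over 96 results and 820 alternatives, 739 kept their value or side of the threshold, 52 moved, 22 became weaker, 7 stronger and 0 reversed. Most of those kept were list percentiles: 323 of 346 for marked counts and 328 of 333 for medians, where many random medians were 0. List contrasts kept 41 of 42. Elsewhere, 4 of 8 were kept for peaks per library, 0 of 10 for overlap, 6 of 6 for agreement and 20 of 43 for annotation. Position along genes kept 4 of 6, marked genes 12 of 18, library differences 0 of 3 and chromosomes 1 of 5. The cause of the changes was not tested. Pearson's r stayed between 0.968 and 0.989 and Spearman's rho between 0.952 and 0.977. Depth is unknown, so what it limits could not be measured. No paired analysis was possible because there is 1 group.

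Merging peaks within 1 kb gave 54396 peaks (139.7 Mb) in library 1 and 47019 (116.7 Mb) in library 2. Of library 1's peaks, 65.1% overlapped library 2 by at least 1 base, 32.5% at 80%, 49.7% with a -log10 q of at least 2 and 41.4% after merging; of library 2's, 81.4%, 52.9%, 74.4% and 66.5%. The Jaccard index was 51.7% with the stricter q and 66.2% after merging. Shares of bases in the pooled list were 16.2% promoter, 7.79% coding exon, 6.89% 3' UTR, 60.8% intron and 4.65% intergenic. After merging, promoter was 16.5%, coding exon 7.201% and intron 61.3%. A 2 kb window gave 29.6% promoter, 6.86% coding exon, 6.16% 3' UTR, 50.9% intron and 3.95% intergenic. Promoters at gene 5' ends held 0.413%. Leaving out each library in turn gave coding exon 8.34% to 8.86%, 3' UTR 6.91% to 7.09% and intron 58.6% to 59.9%. The ratio of coverage downstream to upstream of the gene midpoint was 2.15 in the pooled list and 2.24 to 2.33 by library. Genes overlapping no other gene left 3332 marked. The median difference of the libraries was 3.72 with the stricter q, 2.97 after merging and 0 with equal bases, which that scaling largely sets. X minus autosomes was -26.8 in the pooled list, -28.3 after merging and -27.1 to -26.7 by library.

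The following are percentiles of marked members unless said otherwise. Progenitor genes stood at 2.44 to 4.15 by library, 2.58 in the pooled list, 3.425 after merging, 4.765 at the 20% limit, 2.735 downstream of the midpoint and 20.8 without overlapping genes. Clustered protocadherins stood at 88.8 to 99.8 by library, 86.9 at the 20% limit and 69.2 downstream of the midpoint; their median stood at 70.6 downstream of the midpoint and 90.1 without length matching. Without overlapping genes, the glial list stood at 4.29, sensory ganglion at 4.38, skeletal muscle at 9.335, epidermis at 4.62, forebrain at 2.85 and posterior Hox at 11.3, and the median of the disease list at 94.5. Without length matching, the medians of the pan-neuronal and disease lists stood at 97.02 and 97.3. The glial list stood at 2.57 without X members, and posterior Hox at 3.135 at the 20% limit. Inhibitory genes stood at 1.51 in the pooled list, 1.84 after merging, 1.69 downstream of the midpoint and 2.165 without length matching. Anterior Hox genes stood at 0.315 without replicate 1 and 7.60 without replicate 2, and at 0.570 at the 20% limit. Ribosomal minus housekeeping genes differed by 45.4 points downstream of the midpoint, while the share of reassignments reaching their difference in marked shares, which kept its direction, was 17.33% without replicate 1 and 7.65% without replicate 2.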

Other observations

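All values here were chosen only after seeing the data, and none was weighed against an explanation. The 10 peaks of highest fold all touched coding exon and UTR. The highest lay in Zfp27 (chromosome 7, 29891658 to 29896938, fold 11.99), followed by Zfp329 (11.9), Zfp810 (11.6), Zfp354c (11.4), Zfp369 (10.7) and Zfp68 (10.5). Zfp606, Ppp2r3d, 2610008E11Rik and Zfp873 followed at 10.3, 10.3, 10.2 and 10.2.

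Within the middle 50% of 2274 marked genes of at least 10 kb that overlapped no other gene, exons were covered at 67.1% and introns at 46.7% on average. Exons were higher in 1822 genes and introns in 405. Library 1's own peaks gave 61.3% and 42.2%, and library 2's 54.4% and 36.6%. Far from annotated genes, 120 domains lay more than 10 kb from any gene and held 78.9 kb together. A single one reached 5 kb: a domain of 6.17 kb on chromosome 5 (104582162 to 104588334) with a highest fold of 8.18, covered at 69.3% by library 1's own peaks and 72.9% by library 2's, 59.6 kb from BC005561, the nearest protein-coding gene (56.2% covered).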
